A study of Solanum lycopersicum with 30 samples.

How the data were processed

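RNA was measured in 30 libraries of tomato leaf, made of 10 groups with 3 libraries each. The groups cross 2 tissues, vein-enriched and intervein, with a first time point T0 (watered), T1 (watered or drought) and T2 (watered or recovered). Per the labels' protocols, each library of a group came from a separate plant, leaf 4 was taken, both tissues were dissected from it, and stranded mRNA libraries were pooled and read as single reads of 75 nt in a pair of sequencing runs of the same pool. The labels give no batch per library.

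Per the submitters' processing notes, FastQC 0.11.5, HISAT2 2.1.0, StringTie 1.3.3b and DESeq2 1.20.0 were used. Per the file headers, the deposited counts form a gene count matrix from the KBase platform, with 1 whole-number count per gene and library and no normalization. The genome build, the annotation version and the handling of reads that map to more than 1 gene are not given in the sources used here, so the values of genes with near-identical copies, and of overlapping genes, are uncertain. The authors also deposited, for drought against watered plants at T1 in each tissue, a mean level, a log2 fold change with its standard error, a test statistic, which is a score with no fixed range, and a p-value with its adjusted value. These columns of the authors were described and compared with the count test, and were not used in it. All 30 count columns were matched to samples by name.

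The count table held 35596 rows, of which 34429 carried Solyc identifiers (the tomato gene models) and 1167 carried ENSRNA identifiers (the prefix that Ensembl Plants uses for its non-coding RNA models). In 11899 rows every library had 0 counts. The files pair these identifiers with protein database entries but not with gene names, and 0 of the identifiers matched the 41476 genes of the reference table used here, which is of the assembly SLM_r2.1. Genes are therefore given by identifier only. Lists of gene families and pathways had been fixed before the data were examined, as patterns on gene descriptions. With no descriptions to search, these lists held 0 genes and none was tested. The rule for the genes named in the text, also fixed beforehand, took those with the largest positive and negative log2 fold changes among genes with an adjusted p under 0.05, an average of at least 1 CPM over the compared groups and no overlap between the compared libraries (the last condition was dropped for differences of responses). Its condition that a gene has a description could not be met and was dropped, and the number named was lowered to 2 higher and 2 lower genes per comparison because the identifiers have no names.

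Counts were analysed in R 4.3.3 with edgeR 4.0.16. Rows were kept by filterByExpr on the group, which left 19431 rows (19280 Solyc, 151 ENSRNA) with 99.946% of all counts. Libraries were scaled by TMM factors. All 30 libraries entered 1 quasi-likelihood fit (glmQLFit, glmQLFTest, two-sided) with 1 coefficient per group, leaving 20 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over the tested rows of each comparison. A gene was called at an adjusted p under 0.05. There were 12 comparisons, fixed before the data were examined. They are drought against watered at T1 and recovered against watered at T2 in each tissue, vein against intervein at T0 and over the watered groups, the difference between tissues of the T1 and of the T2 response, watered T2 against T0 in each tissue, and the T2 response minus the T1 response in each tissue. CPM values use TMM-scaled library sizes. Where every library of a group had 0 counts, a fold is given as a bound against a floor of 3 counts over that group. With a library of that group left out the floor rises, since fewer counts remain. Such floors and the intervals of low counts cover counting error only.

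Groups of genes were taken from the data themselves, after the named lists proved empty. Tissue-preferred genes were called by edgeR in the 6 T0 libraries alone (699 vein-preferred and 852 intervein-preferred genes). Being chosen on these samples, they are not independent evidence of a tissue difference at T0, but the T1 and T2 libraries had no part in choosing them. For each library a tissue score was computed as the mean log2 CPM (prior count 2) of the vein-preferred genes minus that of the intervein-preferred genes. A drought score was the mean log2 CPM of the 37 genes called higher in both tissues at T1 minus that of the 41 called lower in both, so that its T1 values are fixed by the choice of genes. Group tests used limma 3.58.1 camera on log2 CPM with a preset correlation of 0.01, repeated with an estimated correlation. Single measures per library were compared by two-sided exact permutation tests, which cannot go below p = 0.1 for 3 libraries against 3, with Benjamini-Hochberg adjustment over the 35 tests run. Medians of fitted log2 fold changes were also computed with genes at 0 in a whole group set to their bound, and a second median is given where this moved it by over 0.01.

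The depth per library ran from 2718799 to 13641845 counts. The steps were tested on simulated counts with 200 changed genes. For the vein T1 comparison, with 18953 to 18993 genes in the fit, 0% of genes changed 2-fold, 16% of those changed 4-fold and 62.5% of those changed 8-fold were called, with 0, 1 and 5 false calls. For the difference between tissues of the T1 response the shares were 0%, 0% and 23.5%. Each simulated gene had 1 mean over all groups, apart from the change. Its spread was that of the trend fitted over expression level. Differences in spread among genes of like level, tissue differences and libraries that stand apart were not simulated. These shares and false calls therefore hold for that simpler setting and may differ in the real data.

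Alternatives fixed beforehand were DESeq2 1.42.0, other scaling factors, no filter and a stricter filter on low counts (at least 1 CPM in 3 libraries), fits on the compared libraries alone, the replicate number or plant as a block, and leaving out each library in turn. Leaving out libraries whose tissue genes stood apart, or the ENSRNA rows, was added after seeing the data.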

Results

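Leaves of tomato (Solanum lycopersicum) plants were sampled at a first time point, at the end of a spell without water and after it. The aim was to compare how the vascular part of the leaf and the tissue between the veins respond. Pots held 300 g of soil under 16 h of light and 8 h of dark. T0 was taken at 25 days after sowing and T1 at 29 days, when the drought plants had gone 6 days without water while the controls received 150 mL every other day. By these numbers the last watering of the drought plants came before the age at T0. Per the protocol, T2 was taken 3 days after the return to watering, and the age at T2 is not certain from the labels. Each of the 10 groups had 3 libraries, with total counts of 2718799 (intervein T2 watered 1) to 13641845 (intervein T2 watered 2) and 13740 to 20143 genes detected per library. The files give no gene names, so genes appear under their identifiers.

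**Figure D1:**
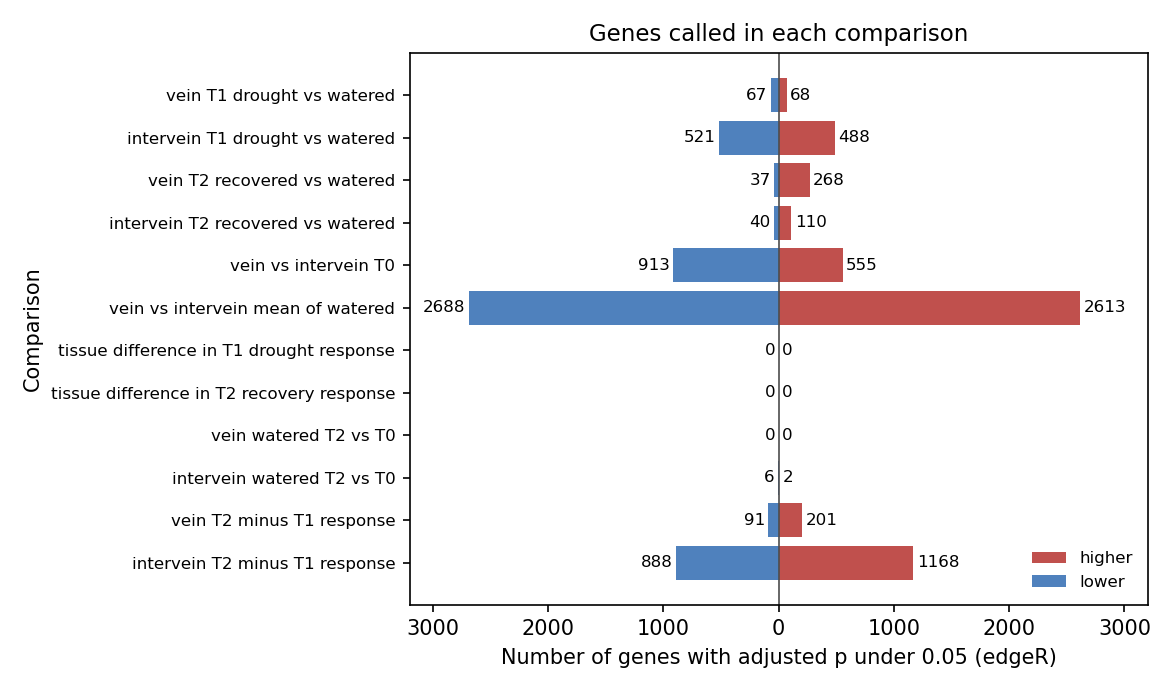
Number of genes called higher (right) and lower (left) by edgeR in each of the 12 comparisons, with the first-named group or response against the second. The tissue comparison over the watered groups called 2613 genes higher and 2688 lower in vein, and both differences between tissues of a response called 0.

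Vein and intervein tissue differed widely under watering. At T0, 555 genes were higher in vein and 913 were higher in intervein. Solyc07g007750 was at 134 ± 18.6 CPM (SD, n = 3) in vein and had 0 counts in the 3 intervein libraries, at least 929-fold higher, and Solyc07g043000 was at least 218-fold higher in vein at 31.4 ± 21.2 CPM (at least 140-fold without vein T0 3). Without intervein T0 3 these bounds were 489 and 115. In the other direction, Solyc05g010040 (31.2 ± 11.6 CPM in intervein) and Solyc10g012050 (22.5 ± 17.0 CPM) had 0 counts in vein and were at least 279-fold and 201-fold lower there, with bounds of 161 and 116 without vein T0 1 and of 185 and 133 without vein T0 3. Over the 3 watered groups of each tissue, 5301 genes were called, 2613 higher and 2688 lower in vein. There Solyc06g059740 and Solyc11g069900 had the largest fitted increases, and Solyc07g041920 and Solyc01g066680 the largest decreases. The T0 count was 543, 538 and 541 without vein 1, 2 and 3, and 397 and 371 without intervein 1 and 2. The count over the watered groups stayed between 4576 and 5220 when any 1 of the 18 libraries was left out.

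The tissue-preferred genes chosen at T0 kept the tissues apart in the watered T1 and T2 libraries, where the tissue score was 1.67 ± 0.30 (SD, n = 3) and 1.11 ± 0.36 in vein and -2.91 ± 0.25 and -2.83 ± 0.35 in intervein. In 2 recovered libraries it did not go with the label. The library labelled vein T2 recovered 2 had a score of -3.14, among the intervein libraries, while vein T2 recovered 1 and 3 had 1.52 and 1.35. The library labelled intervein T2 recovered 1 had a score of 0.49, against -3.03 and -3.13 in intervein T2 recovered 2 and 3. Vein T1 drought 2 lay between the tissues at -0.54, against 1.24 and 1.08 in vein T1 drought 1 and 3. The first principal component of the 2000 most variable genes, which held 30.5% of the variance, placed the first of these libraries at 67.8 and the second at -32.1, where the other vein libraries apart from vein T1 drought 2 (-11.3) lay between -68.8 and -44.9 and the other intervein libraries between 29.9 and 74.2.

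**Figure D2:**
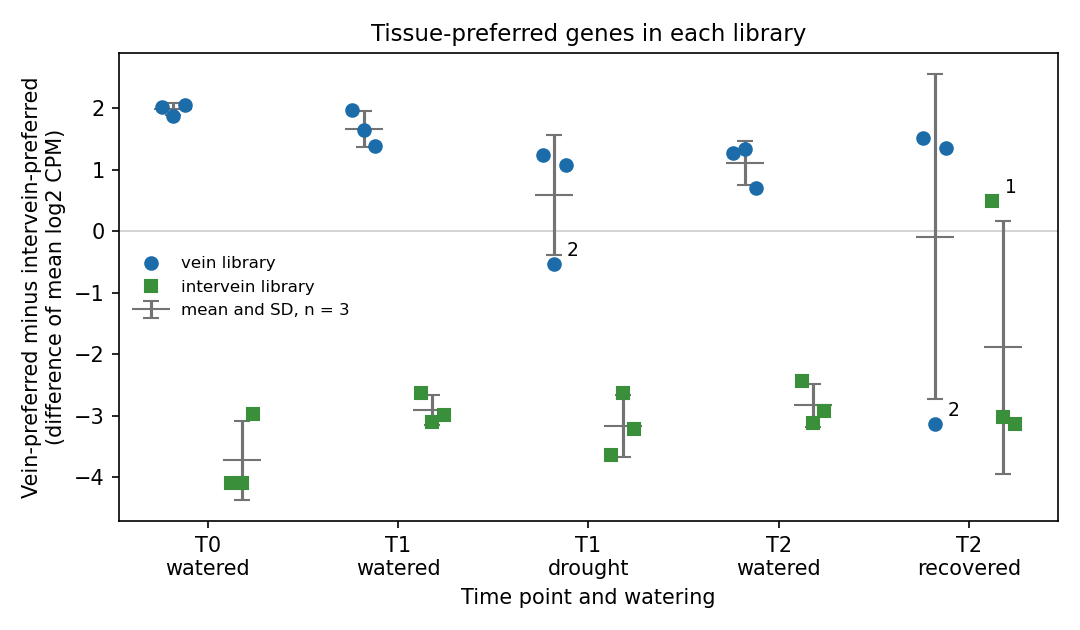
Tissue score of each library, the mean log2 CPM of 699 vein-preferred genes minus that of 852 intervein-preferred genes, by time point and watering. Circles are vein libraries, squares intervein libraries, bars the mean and SD of 3, and numbered points are vein T1 drought 2 (-0.54), the library labelled vein T2 recovered 2 (-3.14) and the library labelled intervein T2 recovered 1 (0.49).

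After 6 days without water, 135 genes differed in vein, 68 higher and 67 lower than in watered vein (edgeR, adjusted p under 0.05), and 133 of them by at least 2-fold. Genes with 0 counts in one group led the list. Solyc10g078770 rose to 706 ± 567 CPM (SD, n = 3) from 0 counts in the 3 watered libraries, at least 7860-fold (adjusted p = 0.0159 by edgeR) and at least 4280-fold without drought 2 and 4790-fold without watered 1. Solyc06g072130 rose to 384 ± 89.0 CPM, at least 4280-fold (adjusted p = 0.0404), or at least 2600-fold without watered 1. Solyc10g008720 and Solyc05g047590 fell from 15.8 ± 3.72 and 15.4 ± 10.7 CPM to 0 counts, at least 157-fold and 153-fold lower, with bounds of 102 and 99.7 without drought 1 and of 99.7 and 97.2 without drought 2.

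Among the 699 vein-preferred genes, 8 fell and 0 rose in vein under drought. Adjusted over the list alone, 32 fell and 2 rose. Their median log2 fold change was -0.71, with 77.4% below 0 (camera adjusted p = 1.35e-12, and adjusted p = 0.452 with an estimated correlation). Vein T1 drought 2, whose tissue score lay between the tissues, is among these libraries, and without it the median was -0.54. Of the 852 intervein-preferred genes 4 rose and 3 fell, with a median of 0.22 (camera adjusted p = 0.0165, and 0.672 with an estimated correlation), which became -0.03 without that library. Each left-out library lowered the count of 135 calls, to 29, 18 and 65 without drought 1, 2 and 3 and to 10, 14 and 66 without watered 1, 2 and 3. It was 248 without both T2 libraries out of place, 336 in a fit of the 6 compared libraries and 896 by DESeq2.

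In intervein, drought changed 1009 genes, 488 higher and 521 lower. Solyc02g084850 rose most, to 11440 ± 10220 CPM (SD, n = 3) from 0.565 ± 0.635 CPM, a 20300-fold rise (adjusted p = 0.0184 by edgeR). That fold holds against T1 watered alone, since this gene was at 15.3 ± 26.2 CPM at T0 and 214 ± 241 CPM at T2 in watered intervein. Its counts were uneven among the drought plants, with 33 counts in drought 1 against 109428 in drought 2 and 193227 in drought 3, and the fold was 12900 without drought 3 and 13500 without watered 3. Without watered 2, where 3 counts remained, it was 51700 with a 95% counting interval of 17700 to 251000. Solyc03g019820 rose to 201 ± 112 CPM from 0 counts, at least 1330-fold (877 and 743 without watered 1 and 2). Solyc05g014000 fell from 37.4 ± 17.6 CPM to 0 counts, at least 275-fold (181 and 152 without drought 2 and 3). Solyc06g069730 fell from 418 ± 688 CPM to 0.134 ± 0.231 CPM, where 3 counts remained, a 3120-fold difference with a 95% counting interval of 1070 to 15200. That fold rests on watered 3, with 5190 counts against 22 and 330 in watered 1 and 2, and it was 153 (52.3 to 741) without that library and at least 2020 without drought 2, which held the 3 counts.

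Of 151 tested rows of the non-coding RNA models, 32 were called higher and 0 lower with drought in intervein. The rows of these models together took 7.48% ± 4.79 (SD, n = 3) of the counts against 1.10% ± 0.40 in watered intervein (exact permutation p = 0.1, the smallest possible, adjusted p = 0.35). Intervein T1 drought 1 had the largest share, 12.2%, and the fewest genes detected, 13740 against 19203 and 18002 in drought 2 and 3. That library was also low for genes that rose in the others. It had 13 counts of Solyc10g078770 against 3653 and 6683, and 0 of Solyc06g072130 against 1393 and 2374. Of Solyc03g019820 it had 368 against 1709 and 2918. Among the vein-preferred genes 13 rose and 35 fell, and among the intervein-preferred genes 6 rose and 14 fell. Their medians were -0.43 and -0.44 (camera adjusted p = 0.000439 and 0.0101, and 0.649 for both with an estimated correlation). Without drought 2 they were -0.941 and -0.668, and the second was -0.699 and -0.154 without watered 1 and 3. Adjusted over each list alone, 14 rose and 45 fell of the first and 3 rose and 7 fell of the second. The 1009 calls became 644 and 219 without drought 2 and 3 and 205 and 337 without watered 2 and 3, and 980 without drought 1. A fit of the 6 compared libraries called 0 and DESeq2 called 2601.

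Drought moved 78 genes in the same direction in both tissues, 37 higher and 41 lower, where independent lists would share 1.71 and 1.8, and 0 genes were called in opposite directions. Of the 135 vein calls, 97.8% had the same sign in intervein. Across all tested genes the log2 fold changes of the tissues correlated with Pearson r = 0.504 and Spearman rho = 0.499, a description over genes, which are not independent replicates. The tissues came from the same plants by the protocol, so differences between plants can add to this overlap. It was 21, 14 and 41 genes without vein drought 1, 2 and 3, 8, 12 and 49 without vein watered 1, 2 and 3, and 192 without intervein drought 1. Without intervein drought 3 and watered 1, 2 and 3 it was 25, 49, 25 and 48. The overlap was 136 without both T2 libraries out of place and 24 without vein T1 drought 2 as well. It was larger by DESeq2, and 0 in fits of the compared libraries alone, where intervein had 0 calls.

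Whether the tissues responded differently was tested as a difference of responses. At T1, edgeR called 0 genes, with 1098 at an unadjusted p under 0.05, and DESeq2 called 72. The larger number of calls in intervein than in vein is thus not shown to be a difference in response. At T2, edgeR also called 0, with 1045 at an unadjusted p under 0.05 and 82 by DESeq2. In the T1 test, intervein-preferred genes had a median difference of 0.66 log2 units towards vein (camera adjusted p = 6.4e-07, and 0.691 with an estimated correlation), with 0 of 852 called. It was 0.321 and 0.428 without vein T1 drought 2 and intervein T1 watered 3, and 0.401 without vein T1 drought 2 and both T2 libraries out of place. Vein-preferred genes had a median of -0.259 (camera adjusted p = 0.0204, and 0.691 with an estimated correlation), or -0.0333 without those 3 libraries. In the T2 test the medians were -0.923 for vein-preferred and 0.967 for intervein-preferred genes. Without both T2 libraries out of place they were 0.375 and -0.232.

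At T2, 305 genes differed between recovered and watered vein, 268 higher and 37 lower. Solyc02g085590 was at 25.5 ± 12.4 CPM (SD, n = 3) in recovered vein with 2 counts left in watered vein, a 318-fold difference with a 95% counting interval of 88.0 to 2630, or at least 153-fold without watered 1, which held both counts. Solyc11g069960 was 208-fold higher at 206 ± 290 CPM, where the library labelled vein T2 recovered 2 had 2796 of 3518 counts, and the fold was 39.5 without it and 394 and 139 without watered 1 and 3. Solyc09g089610 fell from 8.94 ± 2.08 CPM to 0 counts, at least 63.0-fold, and Solyc01g017860 fell at least 39.2-fold, with bounds of 34.5 and 21.5 without recovered 3. Intervein-preferred genes were among those that rose. Of the 852 intervein-preferred genes, 28 rose and 1 fell, or 186 and 5 adjusted over the list alone, with a median of 0.97 (camera adjusted p = 2.44e-13, and 0.396 with an estimated correlation). Without the library labelled vein T2 recovered 2, 0 genes were called and the median was 0.15, and without both libraries out of place edgeR called 0 genes with 2143 at an unadjusted p under 0.05. The count was 1121 without recovered 1, 14 without recovered 3, 0 without any 1 of the 3 watered libraries, 0 in a fit of the 6 compared libraries and 1713 by DESeq2.

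In intervein at T2, 150 genes differed, 110 higher and 40 lower in recovered plants. Solyc04g049340 and Solyc02g085480 were at 26.2 ± 20.04 and 22.3 ± 12.6 CPM (SD, n = 3) in recovered plants, with 0 counts in the 3 watered libraries. They were at least 220-fold and 187-fold higher, or 93.5-fold and 79.6-fold without watered 2. In intervein at T0 these genes were at 10.9 ± 9.2 and 12.8 ± 10.1 CPM. Solyc01g100760 was 11.8-fold lower in recovered plants, at 11.7 ± 2.59 against 139 ± 82.0 CPM (7.84-fold without watered 3). Solyc01g007890 was 10.3-fold lower, at 3.45 ± 0.84 against 35.5 ± 13.7 CPM. At T0 in intervein they were at 14.7 ± 6.75 and 20.6 ± 3.16 CPM. The T2 watered libraries thus lay away from T0 for Solyc04g049340, Solyc02g085480 and Solyc01g100760. These 3 differences are therefore not shown to be effects of recovery. Of the 699 vein-preferred genes 5 rose and 0 fell, with a median of 1.04, or 1.00 with genes at 0 in a whole group set to their bound (camera adjusted p = 2.9e-06, and 0.762 with an estimated correlation). That median was 0 without the library labelled intervein T2 recovered 1. The recovered against watered contrast shared 53 calls between tissues, 48 higher and 5 lower, where independent lists would share 1.52 and 0.0762. Without both libraries out of place, without the library labelled vein T2 recovered 2 alone and without any 1 vein watered library, vein had 0 calls, so none could be shared. Across all tested genes the fold changes of the tissues correlated with Pearson r = 0.281 and Spearman rho = 0.457, and with 0.302 and 0.467 without both libraries out of place. The overlap was 132 and 4 without vein recovered 1 and 3, 16, 13 and 33 without intervein recovered 1, 2 and 3, and 15, 10 and 2 without intervein watered 1, 2 and 3. The 150 calls became 47 and 33 without recovered 1 and 2, and 86, 28 and 7 without watered 1, 2 and 3. They were 115 without both libraries out of place, 0 in a fit of the 6 compared libraries and 1383 by DESeq2.

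Few of the genes that drought changed at T1 were still changed in the same direction at T2. In vein it was 0 of 135 by edgeR, with 3 at an unadjusted p under 0.05 and 29 by DESeq2. In intervein it was 1 of 1009, with 29 and 34, and 26 genes were called in the opposite direction at T2. The 1 gene, Solyc08g041710, named after its values were seen, was at 48.4 ± 14.02 against 17.96 ± 7.24 CPM (SD, n = 3) at T1 and at 29.5 ± 1.91 against 11.3 ± 2.18 CPM at T2. Its call at both times depended on the libraries used. Without both libraries out of place, or without intervein T2 recovered 1 alone, 0 higher genes and 1 lower gene were called at both times. The count was 0 without T1 drought 2 or 3, T1 watered 2 or 3, T2 recovered 2 or any 1 T2 watered library of intervein, and 3 without T1 drought 1. Independent lists would share 2.76 higher and 1.07 lower genes in intervein. Genes that fell short of a call at T1 are not in these counts. Solyc02g085590, called higher in recovered vein at T2 and looked up afterwards, was not called in vein at T1. It was at 110 ± 17.9 against 1.74 ± 0.74 CPM there, and at 25.2 ± 30.7 CPM in watered vein at T0. Most of the T1 calls lay on the other side of the watered level at T2. The sign at T2 was that of T1 for 31.1% of the vein calls and 22.4% of the intervein calls. The genes that rose in intervein at T1 had a median log2 fold change of -0.42 at T2, and those that fell had 0.78. Without both libraries out of place these shares were 21.5% and 24.4%.

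The drought score shows these signs library by library for the 78 genes shared by the tissues, which are among the T1 calls, so it is not separate evidence. It was 4.66 ± 0.43 (SD, n = 3) in vein and 4.04 ± 1.32 in intervein under drought at T1, by construction of the score, and intervein drought 1 was lowest with 2.64. The drought-higher genes averaged 5.41 log2 CPM in that library against 7.12 and 7.53 in drought 2 and 3. Its drought-lower genes averaged 2.77 against 2.92 and 2.27. At T2 the score was -1.31 ± 0.68 in recovered and -0.19 ± 0.69 in watered vein, and -1.43 ± 0.06 in recovered and 0.12 ± 0.89 in watered intervein (exact permutation p = 0.2 and 0.1, adjusted 0.538 and 0.35, where 0.1 is the smallest possible). Watered T2 replicate 3 had the highest T2 score in both tissues, 0.56 in vein and 1.11 in intervein. At T0 the score was -1.33 ± 1.13 in vein and -0.85 ± 0.69 in intervein. Vein T0 2 was at -0.02, against -1.96 and -2.01 in vein T0 1 and 3.

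**Figure D3:**
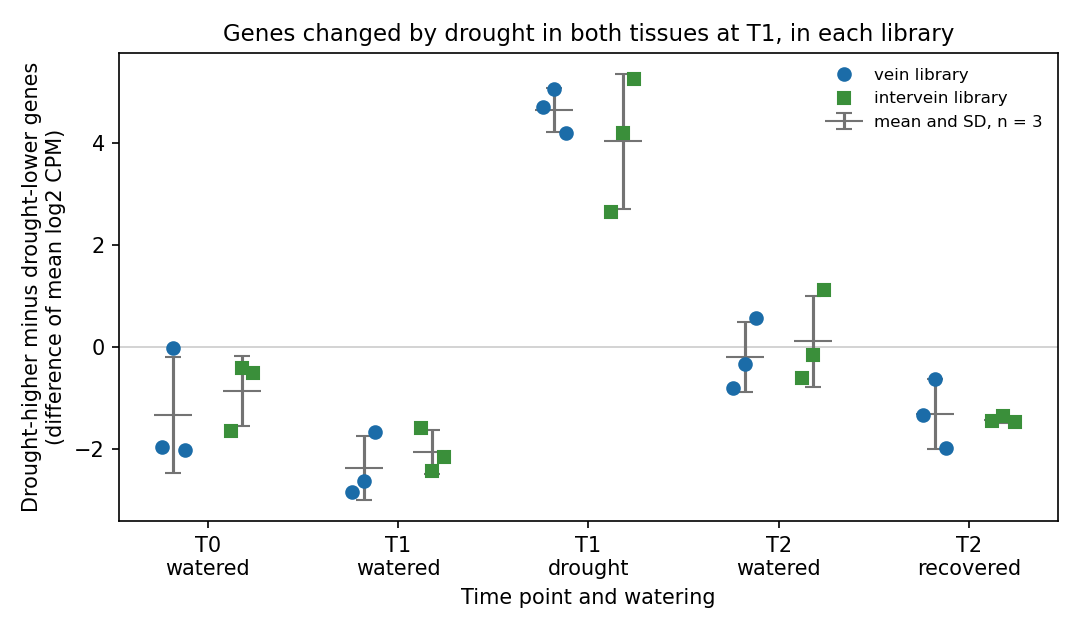
Drought score of each library, the mean log2 CPM of 37 genes higher under T1 drought in both tissues minus that of 41 genes lower in both, by time point and watering. Circles are vein and squares intervein libraries, with the mean and SD of 3, and the T2 watered libraries (-0.80 to 1.11) lie above most of the T2 recovered ones (-1.99 to -0.62).

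The change in response from T1 to T2 was tested directly. In vein 292 genes differed between the responses, 201 with a higher and 91 with a lower fold change at T2, and in intervein 2056 did, 1168 higher and 888 lower. Of the 37 genes higher under drought in both tissues, 21 had a lower response at T2 in vein and 27 in intervein, and of the 41 lower ones, 27 and 34 had a higher response, though these genes were picked for their T1 change. The largest fitted differences were those of Solyc07g020870 and Solyc04g050730 (higher at T2) and Solyc08g077900 and Solyc06g072130 (lower) in vein, and of Solyc12g049400 and Solyc03g005775 (higher) and Solyc03g019820 and Solyc08g077900 (lower) in intervein. The vein count ranged from 41 (without T2 watered 2) to 499 (without T2 recovered 1) over the 12 libraries left out in turn and was 184 without both libraries out of place. The intervein count ranged from 900 (without T2 watered 3) to 2239 (without T2 watered 1).

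Few genes were called between watered plants of T2 and T0. Few calls do not mean few differences, since 16% of simulated 4-fold changes in vein T1 were called. In vein edgeR called 0, with 1727 at an unadjusted p under 0.05 and 284 by DESeq2. In intervein edgeR called 8, of which 2 were higher and 6 lower at T2, and 2518 had an unadjusted p under 0.05. Solyc01g100760 rose 9.44-fold, from 14.7 ± 6.75 to 139 ± 82.0 CPM (SD, n = 3), or 6.26-fold without T2 watered 3. Solyc10g009190 rose 6.81-fold, or 10.2-fold without T0 2. Solyc02g085480 and Solyc08g065470 fell from 12.8 ± 10.1 and 12.5 ± 1.22 CPM to 0 counts, at least 107-fold and 105-fold, or 45.7-fold and 44.6-fold without T2 watered 2. Solyc01g100760 and Solyc02g085480 are also named in the T2 recovered comparison of intervein, which uses the same watered T2 libraries. The 8 calls became 0, 0 and 5 without T0 libraries 1, 2 and 3, 2 and 0 without T2 watered 2 and 3, and 624 by DESeq2. They were also 0 in a fit of the 6 compared libraries, with no filter on low counts and with the replicate block. Without vein T1 drought 2 and both T2 libraries out of place they were 0 as well.

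In the authors' deposited table, 867 genes in vein (390 higher, 477 lower) and 2433 in intervein (1000 higher, 1433 lower) had an adjusted p under 0.05 for drought against watered at T1. Of the genes called here by edgeR, 134 of 135 in vein and 1007 of 1009 in intervein were also called in the authors' deposited table, all in the same direction by its fold change. The test statistic in the authors' deposited table had the opposite sign to its fold change in each of the 22182 vein and 21295 intervein rows with a fold other than 0. Among the genes called in the authors' deposited table, a log2 fold change beyond 20 in size was given for 32 in vein and 33 in intervein, up to 44.5 and 38.5.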

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

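The tests in this part on single libraries, on non-coding RNA rows and on the T2 signs were chosen after the results were seen; the counts over other splits of the samples were set before.

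The response to drought differed between T1 and T2 by a test of the difference itself, with 292 genes called in vein and 2056 in intervein. Among 25 arrangements that exchanged drought and watered labels within each time point, the real one included, 1 gave as many calls in vein, where the highest of the others was 35, and 1 in intervein, where it was 373. The 373 came from exchanging intervein T1 drought 1 with T1 watered 3. These arrangements also mixed drought and watered libraries within T1, so an effect of drought at T1 alone could make the real count the highest. They therefore cannot tell whether the response changed between T1 and T2. A share of 1 in 25 is also the smallest that 25 arrangements can give.

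Whether these counts rest on changes of sign was not tested. The 37 genes higher under drought in both tissues had intervein median log2 fold changes of 2.5 at T1 and -0.48 at T2. The 41 lower genes had -3 and 0.654, so by these medians loss of the T1 change made up most of the difference. A pattern of signs stands beside the counts, since only 22.4% of the intervein T1 calls had the same sign at T2. The libraries out of place by tissue are argued against as its cause, since the share was 24.4% without them, and so is a single T2 library, since the highest share over the 6 left out in turn was 33.8% (without watered 3). Recovered plants that went past the T0 level stay open, since the intervein drought score of recovered minus T0 libraries was -0.575, within 1 SD of the T0 libraries (-1.43 ± 0.06 against -0.85 ± 0.69, SD, n = 3). In vein that difference was 0.0237, and the mean of both tissues was -0.276 (stratified exact permutation p = 0.53, adjusted 0.53). Another candidate explanation that stays open is that the watered plants at T2 were themselves drier, or older, than at T0, since their drought score was higher by 1.06 on average (stratified exact permutation p = 0.07, adjusted 0.105, over 400 arrangements, two-sided). The recovered libraries lay 1.33 below the watered ones in the same kind of test (p = 0.01 by exact permutation, adjusted 0.03), which restates the signs for 78 of the T1 genes, and both tissues came from the same plants by the protocol, so these p-values are too small, and age cannot be told apart from water status here because each T2 group has 1 age.

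A further pattern is that of the T2 recovered libraries whose tissue genes did not go with their labels: for the library labelled vein T2 recovered 2, a score over 201 other genes, which differed between the tissues in the watered T1 libraries, was -3.99, inside the range of the other intervein T1 drought and T2 libraries (-4.06 to -2.25), and its vein-preferred genes averaged 2.45 log2 CPM, no higher than in those libraries (0.90 to 2.88), which argues against a mixture with much vein tissue and is consistent with intervein tissue under a vein label. For the library labelled intervein T2 recovered 1, vein tissue free of intervein tissue is argued against, since its intervein-preferred genes averaged 4.292 log2 CPM, above the 7 other vein T1 drought and T2 libraries (3.39 to 3.73, SD 0.117), and the score over the 201 genes was -1.09, below theirs (-0.60 to 1.68). Its vein-preferred genes averaged 4.78, above the other intervein libraries, so a mixture of tissues in dissection is a candidate explanation, but whether it was mainly vein tissue under a wrong label cannot be told apart because vein T1 drought 2, under a vein label, had a like mean of 4.267. An effect of recovery itself is argued against by the remaining libraries, whose tissue scores were 1.35 or more in vein and -3.03 or less in intervein. Each of these libraries has a partner out of place in the other group, as an exchange between the groups would need, although their replicate numbers differ. An exchange of unmixed tissues would also need vein tissue free of intervein tissue under the intervein label, which is argued against above. Vein T1 drought 2 had no such partner in intervein T1 drought, with tissue scores of -3.64 to -2.64. An exchange was not tested.

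The third pattern is the share of counts on non-coding RNA models in intervein T1 drought, 7.48% on average. Structural RNA carried over into single libraries may account for the share, since a watered library, vein T0 2, reached 10.69% and 7 of the 18 watered libraries reached the lowest drought value of 2.62%; an effect of drought on these RNAs stays open, as the design cannot reach an exact permutation p under 0.1. Of the 1009 intervein calls 32 were such rows, and 999 genes were called with the rows left out. Leaving them out could remove few calls directly, so it does not test whether a library with a high share differs in other ways. Without intervein T1 drought 1, the drought library with the largest share, 980 genes were called.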

How the results depend on the processing

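Leaving out the libraries out of place by tissue or the ENSRNA rows, the alternatives of the overlaps other than DESeq2 and left-out libraries, and the alternatives of the T2 overlap, the gene-group medians and the folds of named genes were added after seeing the data; the rest were set before. The calls of vein against intervein over the watered groups stayed within 1.5 times of 5301 under every alternative run, from 4065 to 6260. Scaling by RLE factors, the stricter filter and leaving out the ENSRNA rows moved no count of the 12 comparisons by over 1.5 times. DESeq2 gave more calls: 896 for vein T1, 2601 for intervein T1, 1713 for vein T2, 1383 for intervein T2, 2894 for the tissues at T0, 72 and 82 for the tissue difference of the T1 and T2 responses, 284 and 624 for watered T2 against T0 in vein and intervein, and 1363 and 3724 for T2 minus T1 in vein and intervein. It called 29 and 34 T1 genes again at T2 in vein and intervein and 476 genes in both tissues at T1; an unadjusted p under 0.05 at T2 kept 3 and 29. A fit of the compared libraries alone, with fewer residual degrees of freedom, gave 336, 0, 0 and 0 for vein T1, intervein T1, vein T2 and intervein T2, 1 and 0 for watered T2 against T0 in vein and intervein, 675 and 633 for T2 minus T1, an overlap of 0 between tissues at T1 and 0 intervein genes called again at T2. With no filter on low counts vein T2 had 197 calls and intervein watered T2 against T0 had 0. The cause of these shifts was not tested.

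Without both libraries out of place, vein T1 had 248 calls, vein T2 had 0, vein T2 minus T1 had 184 and the T1 overlap was 136; without vein T1 drought 2 as well, these were 29, 0, 146 and 24, and intervein watered T2 against T0 had 0. The median of intervein-preferred genes in vein T1 drought reversed from 0.22 to -0.03 (-0.0264 without all 3, and -0.0256 to 0.385 with single libraries left out, lowest without vein T1 drought 2).

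With single libraries left out in turn, calls ranged from 10 to 66 for vein T1, 205 to 980 for intervein T1, 0 to 1121 for vein T2, 7 to 129 for intervein T2, 371 to 1376 for the tissues at T0, 4576 to 5220 over the watered groups, 0 to 1 and 0 to 3 for the tissue difference of the T1 and T2 responses, 0 to 2 and 0 to 6 for watered T2 against T0 in vein and intervein, and 41 to 499 and 900 to 2239 for T2 minus T1. Genes called again at T2 ranged from 0 to 2 in vein and 0 to 3 in intervein (1 lower and 0 higher without T2 recovered 1, against 1 higher and 0 lower with all libraries), and the T1 overlap from 8 to 192. In each such fit the group had 2 libraries left.

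The replicate numbers were not taken as pairs, since the labels do not say whether they mark the same plant. Of 15 vein and intervein pairs with the same number, 6 had deviations that correlated above 0.1 (range -0.241 to 0.307). The vein library correlated best with its own number in 9 of 15, where unpaired numbers would on average do so in 1 of 3. In T2 recovered, pairs 1, 2 and 3 had 0.252, 0.307 and -0.241, and pairs 1 and 2 were best matches. Deviations in that group carry the libraries out of place by tissue, so those pairs cannot tell whether numbers mark plants. Pairing is not excluded. With the replicate block, vein T2 had 160 calls, intervein watered T2 against T0 had 0, and the genes called again at T2 were 1 in vein and 0 in intervein; with the plant as a random replicate block the tissue difference of the T1 response had 1. The block moved no other count of calls by over 1.5 times.

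Over 36 named-gene results, 644 alternatives gave 430 with an adjusted p under 0.05, 214 above it and 0 with another sign. These genes were picked for the largest fold changes, mostly without overlap between the compared libraries, so the kept signs are not separate evidence. Alternatives in which the gene was not tested or had no adjusted p were not counted. The tests of fixed gene lists, with their alternatives, were not run, since the lists held 0 genes. Depth limits genes near the floor of 3 counts per group, and 4-fold changes were called for 16% of simulated genes in vein T1.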

Other observations

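The tests of neighbouring genes and of the most abundant genes were chosen after the data were seen; the counts over other splits of the samples were set before for the differences of responses and after their results for the rest.

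Neighbours were taken as genes next to each other by identifier on the same chromosome among the 19280 tested Solyc genes. Untested genes may lie between them. In several comparisons neighbours were called in the same direction more often than on average in 1000 shuffles of the calls. Near-identical copies, whose values are uncertain here, were not set apart. Vein against intervein over the watered groups had 964 such pairs, against a mean of 725 and a highest of 805 in the shuffles. Vein against intervein at T0 had 91 pairs (mean 58.9, highest 83), intervein T2 minus T1 had 148 (mean 111, highest 144) and vein T2 minus T1 had 11 (mean 2.58, highest 9), each with a permutation p of 0.001, the smallest that 1000 shuffles can give. Intervein T1 drought had 41 pairs against a mean of 24.7 and a highest of 41 (p = 0.002 by permutation). Vein T1 drought had 2 pairs (mean 0.476, highest 4, permutation p = 0.08) and intervein T2 had 0. Over these 8 tests the Benjamini-Hochberg adjusted values were 0.002 for the first 4, 0.0032 for intervein T1 drought and 0.053 for vein T2, which had 8 pairs (mean 3.7, highest 11).

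The share of counts on the 50 most abundant genes differed between watered intervein libraries of the same group. It was 31.6% in T0 2 and 14.6% in T0 3, and 35.1% in T1 3 and 14.1% in T1 1.

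Other splits of the same samples were counted for each of the 12 comparisons. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 135 calls in vein T1 against a highest of 0 in the other 9, 1009 against 426 in intervein T1, 305 against 0 in vein T2, 150 against 6 in intervein T2, 1468 against 0 for the tissues at T0 and 8 against 1 for watered T2 against T0 in intervein, so that 1 of 10 splits was as large in each. The 426 calls of intervein T1 came from the split that exchanged drought 1 with watered 3. For watered T2 against T0 in vein all 10 splits gave 0. For the tissues over the watered groups, 1 of 25 arrangements drawn was as large as the real 5301, with a highest of 722 in the others. Chance arrangement of the tissue labels is argued against there, at the smallest share that 25 arrangements can give. For the tissue difference of the T1 and of the T2 response the real count was 0, so that 25 of 25 arrangements were as large, with a highest of 0 and of 2 in the others.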
